A study of Mus musculus with 6 samples.

How the data were processed

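Small RNA of mouse myocardium was sequenced in 6 libraries, 3 taken at a post-mortem interval of 0 h and 3 at 6 d. The post-mortem interval is the time between death and sampling. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a NEBNext small RNA kit. Per the submitters' processing notes, FastQC, Trimmomatic 0.39, cutadapt 2.8 and STAR 2.5.3a were used, with no role given. The counting tool, the miRNA annotation and the genome build are not given in the sources used here, so no coordinates are printed. The labels do not say that the samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

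Each deposited file holds the same 984 mature miRNAs, and the 6 files do not share 1 unit. The deposited file of 0 h replicate 1 holds raw read counts. The other 5 deposited files hold log2 values with 3 decimals. Undoing the log2(x + 1) transform of these deposited files gave values x that were whole multiples of 1 step per library, so that each step is what 1 read is worth. A value counted as whole if a whole multiple of the step, which was estimated from the same values, lay within the rounding of its 3 decimals (0.0005 on the log2 scale either way). This could be tested where that rounding spans less than 0.5 of a read, up to 693 to 714 reads. It held for 2692 of the 2692 nonzero values that could be tested, and 418 of the 3110 nonzero values could not be tested. Larger values carry a rounding error of 0.0347%. The values x of the log2 libraries summed to between 556806 and 1315260, so they are read counts scaled to 1000000 and by a further factor per library, called normalised CPM here, and not plain CPM. The design fixed before the data were examined had foreseen either counts or normalized values in all files, not a mixture. The counts of 0 h replicate 1 were therefore put on the scale of the other 5 with a factor of 0.919, chosen so that the factors of the 6 libraries multiply to 1, as edgeR's factors do. This scale factor is derived and not stated by the authors.

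Because 5 files hold normalized values, the main test was the one fixed for such values: limma 3.58.1 with a trended prior and robust estimation on log2(value + 1), over miRNAs with a value of at least 1 in at least 3 libraries. Of the 984 miRNAs, 470 were tested, and the 514 left out held 0.0114% of the reads. A call is a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low miRNAs. They compare reads scaled within each library, so a rise or fall is relative to the other miRNAs. Absolute amounts were not measured. The quasi-likelihood test of edgeR 4.0.16 on the recovered whole reads, with TMM factors, was added after the data were seen. It tested 363 miRNAs and called 156.

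The 15 miRNA lists were fixed before the data were examined. They cover cardiac and skeletal muscle, endothelium, smooth muscle and pericytes, fibroblasts, red blood cells, leukocytes, other organs, the let-7, miR-30 and miR-15/16 families, the miR-17-92 clusters, the Dlk1-Dio3 cluster, hypoxia, miRNAs often used as qPCR references, and miRNAs numbered 1000 or above. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 15 lists. For precursors with both arms tested, limma was run on the log2 ratio of 5p to 3p reads with 1 read added to each. Composition measures were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1.

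The named miRNAs were chosen by a rule also fixed then. It takes the 8 largest rises and the 8 largest falls among called miRNAs whose groups do not overlap and whose mean is at least 10 CPM, the 5 most abundant miRNAs, and up to 3 of the most abundant tested members of each list. Other list members are given as examples of a list's called members and were chosen after their values were seen.

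Depth was 4468547, 7906563 and 7299595 reads at 0 h and 1889593, 699670 and 617069 at 6 d, counted over the 984 miRNAs. A floor of 3 reads corresponds to 0.463 to 0.730 CPM at 0 h and to 1.91 to 3.97 CPM at 6 d. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Replicates differed by far more than sampling noise, with a chi-square per degree of freedom of 262 or more in each pair, so each library was counted as 1 sample. Rows of miR-199a-3p and miR-199b-3p, of miR-486a-5p and miR-486b-5p, of miR-374b-5p and miR-374c-5p, and of let-7a-1-3p and let-7c-2-3p were nearly identical and share reads, so their values are uncertain.

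The steps were tested on simulated data. Counts were drawn for the 470 miRNAs of 6 d against 0 h with 200 of them changed, in 5 draws. The limma step recovered 25.4% of 2-fold, 77.7% of 4-fold and 99.4% of 16-fold changes, and 4.06% of its calls were false. The simulated counts were scaled with the known factors of the libraries, so the choice of scaling was not tested. The arm ratio step, on 116 precursors with 30 shifted by 3 log2 units, recovered 100% of them with 5.06% false calls. Its log2 ratios were drawn from a normal distribution with an SD of 0.6 and not from reads. Low read numbers and wider spreads, such as the SD of 3.03 of miR-299a at 6 d, were left out. It therefore does not show how well smaller or noisier shifts are found.

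Precursor sequences of 941 of the 984 miRNAs came from GENCODE M21 transcripts. They were compared with the structural RNAs of the same annotation with blastn 2.17.0, at 95% identity over at least 20 bases. The alternatives tried were other scalings, filters, pseudocounts and tests, the replicate numbers as a block, libraries left out in turn, and thinning to the smallest library. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.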

Results

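MicroRNAs were measured in mouse myocardium, the muscle wall of the heart, at 0 h and at 6 d after death, with 3 libraries at each interval. The series is titled as a study of miRNAs for estimating the post-mortem interval. The 0 h libraries held 6558235 miRNA reads on average (SD 1834993, n = 3) and the 6 d libraries 1068777 (SD 712046, n = 3). Between 722 and 760 miRNAs had a read at 0 h and between 513 and 542 at 6 d. After thinning every library to 617069 reads this difference was gone, with 464.8 ± 16.5 miRNAs at 0 h and 490.6 ± 55.0 at 6 d (SD, n = 3 each). The exact two-sided permutation p was 0.1 for the unthinned number, the smallest that 3 against 3 libraries allow, and 0.236 after adjustment over 26 composition measures.

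The heart miRNA miR-1a-3p was the most abundant at both intervals, with 28.9% ± 7.52 of the reads at 0 h and 32.5% ± 12.3 at 6 d (SD, n = 3 each). Its log2 fold change of -0.33 was not past the threshold (limma adjusted p = 0.67). The erythrocyte miRNA miR-451a rose by 2.30 ± 0.35 on the log2 scale (SE, n = 3 each, limma adjusted p = 0.0011), from 1.15% ± 0.13 to 7.99% ± 2.38 of the reads. Of the other abundant miRNAs, miR-99a-5p changed by -2.08 ± 0.31 (limma adjusted p = 0.0010) and the endothelial miR-126a-3p by -1.33 ± 0.32 (limma adjusted p = 0.0095), though miR-126a-3p was not called when scaled by library totals alone (adjusted p = 0.11). The log2 fold changes of miR-148a-3p (-0.30) and of the smooth muscle miR-143-3p (-0.71) were not past the threshold with all libraries, while without 6 d replicate 1 that of miR-143-3p was -1.18 (limma adjusted p = 0.021).

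Over all 470 tested miRNAs, 178 differed between 6 d and 0 h, 75 higher and 103 lower at 6 d. Of these, 175 changed at least 2-fold, 75 upward and 100 downward. The largest rises were of miR-6538, from 0.722 ± 0.053 to 499.5 ± 475.2 normalised counts per 1000000 reads, CPM (log2 fold change 7.62 ± 0.72, SE), of miR-2137, from 0.162 ± 0.281 to 219 ± 291 (6.40 ± 1.01), of miR-206-3p, a skeletal muscle miRNA, from 12.2 ± 3.54 to 1035 ± 381 (6.27 ± 0.38), and of the epithelial miR-200a-3p, from 9.55 ± 2.31 to 695 ± 275 (6.00 ± 0.37), with n = 3 for each mean ± SD and limma adjusted p of 8.8e-05, 0.0014, 5.4e-06 and 5.4e-06. Then came miR-6236 (log2 fold change 5.90), miR-6240 (5.67), miR-664-5p (5.34), whose precursor matches the snoRNA Snora36b over 64 bases at 100% identity, and the epithelial miR-205-5p, from 1.32 ± 1.19 to 71.2 ± 28.9 CPM (SD, n = 3 each). For miR-2137 there were 2 reads at 0 h and 27, 418 and 97 in the 6 d libraries (17.2, 553 and 87.5 CPM), so its level at 6 d was uneven. The pooled ratio of 6 d to 0 h was 1309 with a 95% exact interval of 361 to 10839, which covers counting error only. It was 2293 (632 to 18984) without 6 d replicate 1, 1587 (437 to 13146) without 6 d replicate 3 and 384 (104 to 3206) without 6 d replicate 2. Without 6 d replicate 2 the 6 d mean also fell from 499 to 237 CPM for miR-6538, from 207 to 47.4 for miR-6240 and from 115 to 76.6 for miR-6236. The largest falls were of miR-674-3p (log2 fold change -4.61 ± 0.52), miR-543-3p (-4.55 ± 0.74), miR-139-5p (-4.06 ± 0.38), miR-1964-3p (-3.66), miR-455-3p (-3.50), miR-191-5p (-3.37 ± 0.44), miR-541-5p (-3.34) and miR-340-3p (-3.20). Reads in the 6 d libraries were 9, 2 and 16 for miR-674-3p, 0, 0 and 7 for miR-543-3p and 3, 0 and 4 for miR-455-3p. The size and order of these falls are therefore uncertain. Over the 470 tested miRNAs, all 3 libraries of one interval lay above all 3 of the other for 238 (50.6%, against 10% by chance).

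**Figure D1:**
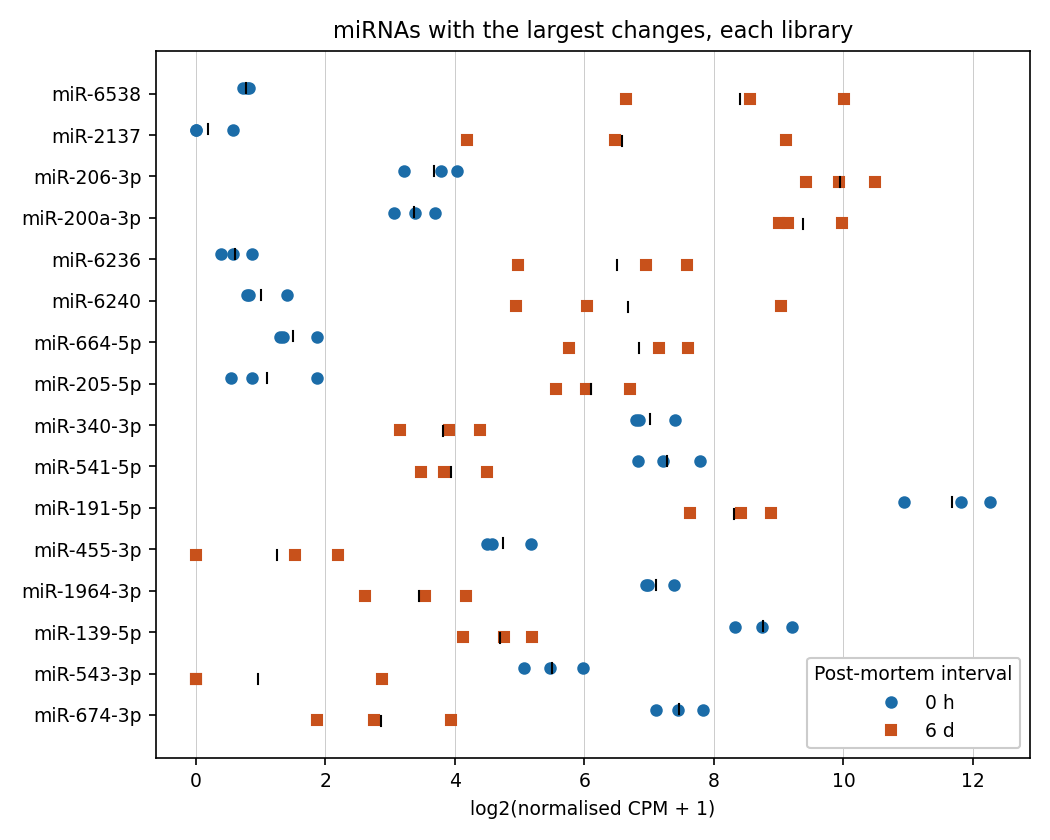
Normalised CPM, as log2(value + 1) on the horizontal axis, of the 8 miRNAs with the largest rise and the 8 with the largest fall at 6 d. Each circle is a 0 h library, each square a 6 d library and each vertical bar the mean of 3 libraries. The miRNAs were selected from those whose 0 h and 6 d libraries do not overlap.

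How many miRNAs were higher or lower depended on the scaling and on read depth. The median log2 fold change of all tested miRNAs was -0.33 on the deposited scale, -0.17 with RLE size factors and 0.02 with library totals alone. With the limma test kept and only the scaling changed, 174 miRNAs were called with RLE size factors, 90 higher and 84 lower, and 123 with library totals alone, 83 higher and 40 lower. Other tests, which also differ in their filter, called 172 of 488 tested miRNAs with DESeq2, 97 higher and 75 lower, and 157 of 363 with limma-voom, 83 higher and 74 lower. The edgeR test called 81 higher and 75 lower of 363, and 142 of its calls were also limma calls in the same direction. With TMM factors recomputed at full depth, limma called 173 miRNAs, 74 higher and 99 lower. After thinning to the smallest library, with new TMM factors, it called 144 of 465, 75 higher and 69 lower. Without 0 h replicate 1, 114 miRNAs were called.

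Of the lists fixed in advance, the miRNAs of other organs stood higher at 6 d. Of 19 tested members 11 rose and 1 fell, also when adjusted over the list alone, and the median log2 fold change was 1.64, or 1.97 above that of all tested miRNAs (camera adjusted p = 0.00010, with 0.27 as the adjusted p with an estimated correlation). By edgeR 10 of 15 rose and 1 fell. The members that rose included miR-200a-3p, miR-205-5p, miR-200b-3p (log2 fold change 4.41), miR-429-3p (4.31) and miR-141-3p (4.09) of epithelia, miR-375-3p (3.01) of endocrine cells, and the liver miRNA miR-122-5p (3.42 ± 0.80, limma adjusted p = 0.0095). Reads of miR-122-5p numbered 3277, 17725 and 18525 in the 6 d libraries, and so were uneven among them. The member that fell was miR-128-3p (-1.50, limma adjusted p = 0.026), which is abundant in brain. It was not called with library totals alone (log2 fold change -1.04, adjusted p = 0.24), nor without 0 h replicate 2 (adjusted p = 0.064), 0 h replicate 3 (adjusted p = 0.083) or 6 d replicate 2 (adjusted p = 0.076). The liver and gut miRNA miR-192-5p had a log2 fold change of -0.32, not past the threshold.

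The miR-30 family, abundant in heart, stood lower. Of 11 tested members 8 fell and 0 rose, against 8 and 1 when adjusted over the list alone (median log2 fold change -1.34, camera adjusted p = 0.016, adjusted p = 0.27 with an estimated correlation). The log2 fold change was -3.03 ± 0.28 for miR-30c-5p, -3.16 for miR-30a-3p and -3.12 for miR-30e-3p. Of the 5p arms only miR-30c-5p and miR-30d-5p (-1.98 ± 0.53) fell, and the other falls were of 3p arms. The call of miR-30d-5p was lost with library totals alone (adjusted p = 0.074). It was also lost without 0 h replicate 1 (limma adjusted p = 0.060), 0 h replicate 2 (0.058) or 6 d replicate 2 (0.058). The 5p arms miR-30a-5p (-0.07), miR-30e-5p (-0.31) and miR-30b-5p (0.82) were not past the threshold with limma. By edgeR 5 of the 11 fell and 1 rose, miR-30b-5p (log2 fold change 1.03, edgeR adjusted p = 0.040). Without 6 d replicate 3 the list was not called (camera adjusted p = 0.066). The list of miR-17-92 and its paralogous clusters, tied to cell proliferation, stood higher. Of its members 8 of 17 were up and 0 down, also when adjusted over the list alone, and 8 of 14 up and 0 down by edgeR (median log2 fold change 1.01, camera adjusted p = 0.0006, adjusted p = 0.61 with an estimated correlation). Among the members that rose were miR-20b-5p (3.45), miR-363-3p (2.51), miR-93-5p (1.86 ± 0.36) and miR-25-3p (1.32 ± 0.30). The miR-17-92 cluster itself, apart from miR-92a and miR-19b, which a paralogous cluster also encodes, had 0 of 6 members called (median 0.18).

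**Figure D2:**
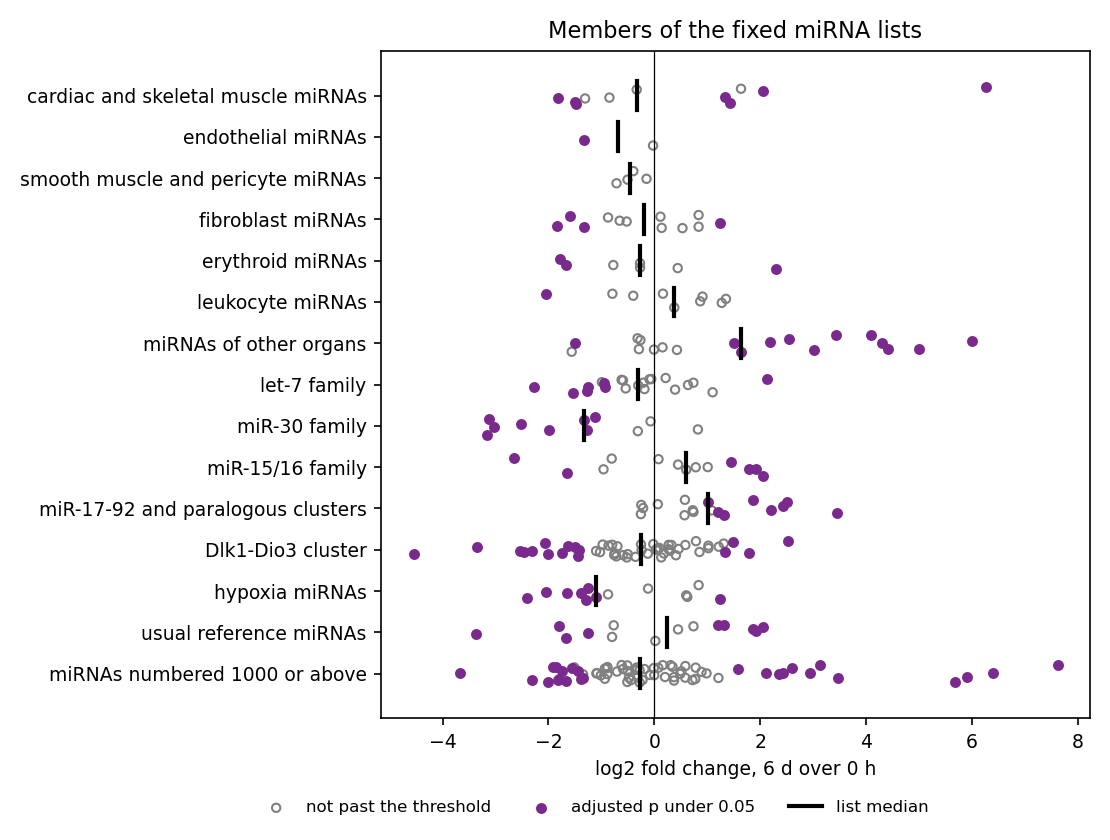
Log2 fold change at 6 d over 0 h of each tested member of the 15 lists. Filled circles are members with a limma adjusted p under 0.05, open circles are the others, and the black bar is the list's median. The medians of the other organ, miR-30 and miR-17-92 lists were 1.64, -1.34 and 1.01.

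The other 12 lists were not called. Among cardiac and skeletal muscle miRNAs 4 of 11 members rose and 3 fell, also adjusted over the list alone, and 4 and 3 of 10 by edgeR. Besides miR-206-3p, its clustered neighbour miR-133b-3p (2.06) and miR-133a-3p (1.43 ± 0.31) rose, while miR-499-5p (-1.48 ± 0.38) and miR-208a-3p (-1.49), which lie within myosin heavy chain genes, fell. So did miR-133a-5p (-1.83, limma adjusted p = 0.0077), the other arm of miR-133a. With library totals alone the calls of miR-499-5p (adjusted p = 0.11) and miR-208a-3p (adjusted p = 0.12) were lost. The median of this list was -0.33 and its mean 0.49, in the direction of the camera test. Of 2 endothelial members 1 fell, of 4 smooth muscle and pericyte members 0 were called, and of 9 leukocyte members 1 fell, each also adjusted over the list alone. The leukocyte member that fell was miR-150-3p, from 5.44 to 0.653 CPM, with 2 reads in all at 6 d. By edgeR 2 leukocyte members rose, miR-142a-5p (log2 fold change 1.31, edgeR adjusted p = 0.034) and miR-223-3p (1.77, edgeR adjusted p = 0.019), and 1 fell. The limma value of miR-142a-5p was 1.27 (adjusted p = 0.071), and it was called with RLE size factors, library totals alone, DESeq2, limma-voom and the replicate block, but not when any 1 library was left out. The smooth muscle members had 0 limma calls, 0 at an unadjusted p under 0.05 and 0 with edgeR. Of 12 fibroblast members 1 rose and 3 fell, against 3 and 4 adjusted over the list alone and 3 and 1 by edgeR, and the camera direction was up while the median was -0.20. Of 7 erythroid members miR-451a rose and miR-486a-3p and miR-486b-3p fell, also adjusted over the list alone, and the edgeR counts of the endothelial and erythroid lists were the same, though neither fall was called with library totals alone (adjusted p = 0.074 and 0.20).

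In the let-7 family 1 of 21 members rose and 6 fell, against 1 and 4 adjusted over the list alone, with let-7g-5p at -2.27 ± 0.37 (limma adjusted p = 0.0014) and let-7i-5p at -0.06, not past the threshold. In the miR-15/16 family 4 of 13 rose and 2 fell, and in the imprinted Dlk1-Dio3 cluster 4 of 51 rose and 12 fell, the same numbers as over the list alone. The fall of miR-127-3p in this cluster was -2.45 ± 0.46. Of 13 hypoxia miRNAs 1 rose and 7 fell, against 2 and 8 over the list alone, with miR-210-3p, the best known of them, at -1.30, a call lost with library totals alone (adjusted p = 0.16). The fry test, which asks only whether a list's members move one way on balance, gave an adjusted p of 0.013 for this list. Of 14 members of the usual reference miRNAs 5 rose and 4 fell, also over the list alone, miR-16-5p by 1.93 ± 0.55 and miR-191-5p by -3.37 ± 0.44 on the log2 scale. The call of miR-16-5p was lost without 0 h replicate 3 (adjusted p = 0.052), 6 d replicate 1 (0.063) or 6 d replicate 2 (0.074). The median of this list was 0.23 and its mean -0.01. Of 71 miRNAs numbered 1000 or above 12 rose and 13 fell, against 12 and 12 over the list alone, with a median of -0.28 and a mean of 0.19. Among the members that fell, only miR-1964-3p and miR-3068-5p had a 6 d mean above 1.33 CPM. The other falls ended under the 6 d floor of 3 reads and are uncertain. By edgeR 1 of 20 let-7 members rose and 3 fell, 5 of 11 in the miR-15/16 family rose and 2 fell, 6 of 35 in the Dlk1-Dio3 cluster rose and 10 fell, 2 of 12 hypoxia miRNAs rose and 6 fell, 5 of 12 reference miRNAs rose and 3 fell, and 9 of 35 miRNAs numbered 1000 or above rose and 3 fell. The medians of the smooth muscle, fibroblast, erythroid, let-7, Dlk1-Dio3 and late-numbered lists, all below 0 on the deposited scale, were above 0 with library totals alone. That of the cardiac and skeletal muscle list was then 0.13 over the same 11 members and -0.15 with miR-499-3p, which passed the filter only there.

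The ratio of the arms of 1 precursor does not depend on the scaling of a library. With 1 read added to each arm it does depend on depth where an arm has few reads. Arms were paired by name, and the miR-199a and miR-199b rows, like the miR-486a and miR-486b rows, share reads. Of 116 precursors with both arms tested, 46 changed this ratio, 23 toward the 5p and 23 toward the 3p arm. Of these 29 moved toward the arm with fewer reads over all libraries and 17 toward the other. The log2 ratio of 5p to 3p fell by 3.25 ± 0.51 for miR-133a and by 3.21 ± 0.47 for miR-200a, and rose by 1.31 ± 0.19 for miR-126a, by 3.09 ± 0.79 for miR-30a, by 4.01 ± 0.58 for miR-382 and by 5.21 ± 0.73 for miR-664, the precursor that matches Snora36b (SE, n = 3 each, limma adjusted p of 0.018 for miR-30a and 0.0021 for the others). For let-7g the log2 ratio fell by 4.30, and its 3p arm had 12 reads at 0 h and 10 at 6 d. With both arms at 10 CPM or more on average 27 of 53 precursors were called. Without that limit, 25 were called when 0 h replicate 1 was left out.

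**Figure D3:**
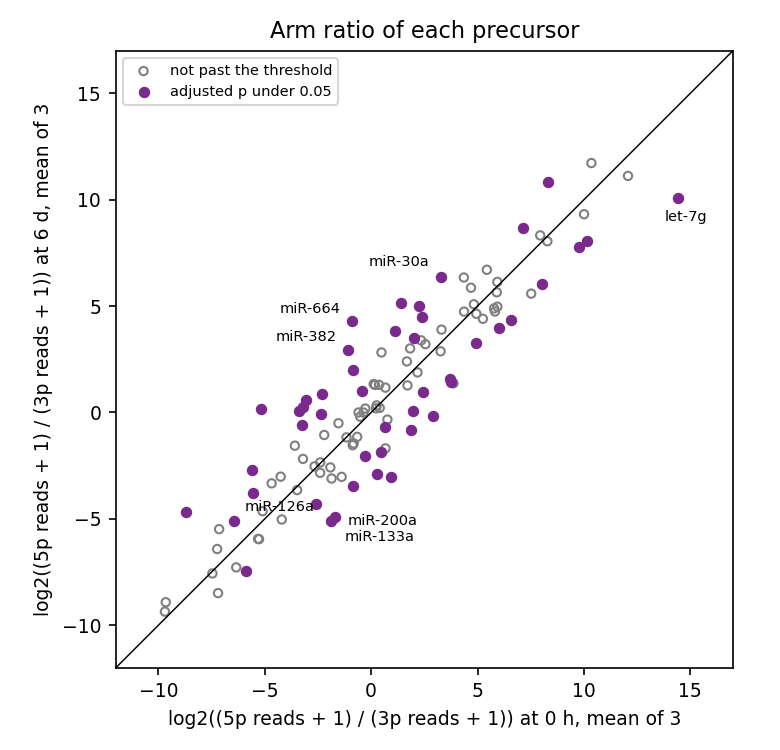
Mean log2 ratio of 5p to 3p reads of each of the 116 precursors at 0 h (horizontal) and 6 d (vertical), each over 3 libraries with 1 read added to each arm. Filled circles are the 46 precursors with a limma adjusted p under 0.05, and the diagonal marks an equal ratio.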

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

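The edgeR test, the recomputed TMM factors, the thinning, the omission of miRNAs numbered 1000 or above, the omission of those that match structural RNA and the block for arm ratios were chosen after seeing the data. No limma call reversed its sign in any setting run. The count of 178 ranged from 114 (without 0 h replicate 1) to 179 when 1 library was left out, and that of 175 with at least 2-fold change from 114 to 177. Arm ratios gave 25 to 49 calls when 1 library was left out, and 27 with both arms at 10 CPM or more, where only 53 precursors were tested. The miR-30 median ranged from -1.62 to -1.22 and its call was lost without 6 d replicate 3, the cause was not tested. The number of miRNAs with a read was lower by 212.7 at 6 d and became higher by 25.85 after thinning, which removes depth. With the replicate block 195 miRNAs were called, 79 higher and 116 lower. The deviations of same-numbered libraries correlated at 0.07, 0.06 and 0.27, not all above 0.1, and 0 h replicate 1 correlated best with 6 d replicate 2 (0.16), so the numbers are not taken to pair the samples.

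The log2 fold change of miR-5099, 0.99 with all libraries, changed sign without 6 d replicate 2 and was then not called. Log2 fold changes nearer 0 changed sign in some settings and were not called where they did. With RLE factors they were 0.20 for miR-126a-5p, 0.076 for miR-145a-5p, 0.17 for let-7i-5p and 0.15 for miR-30a-5p. With library totals alone they were 0.13 for miR-1a-3p, 0.16 for miR-148a-3p, 0.44 for miR-126a-5p, 0.31 for miR-145a-5p, 0.19 for both miR-486b-5p and miR-486a-5p, 0.14 for miR-192-5p, 0.40 for let-7i-5p and 0.39 for miR-30a-5p. With DESeq2 they were 0.079 for miR-1a-3p, 0.18 for miR-126a-5p, 0.048 for miR-145a-5p, 0.0079 for miR-192-5p and 0.22 for let-7i-5p. In the order miR-126a-5p, miR-145a-5p, let-7i-5p and miR-30a-5p they were 0.14, 0.025, 0.11 and 0.0951 with limma-voom, 0.14, 0.064, 0.10 and 0.087 after thinning, and 0.16, 0.035, 0.13 and 0.11 without miRNAs numbered 1000 or above. With edgeR they were 0.089 for miR-126a-5p and 0.14 for let-7i-5p. With 1 library left out the range was -0.84 to 0.30 for miR-1a-3p, -0.23 to 0.18 for miR-126a-5p, -0.41 to 0.022 for miR-145a-5p, -0.26 to 0.74 for miR-146a-5p, -0.68 to 0.087 for miR-192-5p, -0.31 to 0.19 for let-7i-5p, -0.91 to 0.55 for miR-30a-5p, -0.18 to 0.34 for miR-195a-5p and -0.032 to 2.05 for miR-5099, which without 6 d replicate 1 was called at its highest value. The cause was not tested.

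With copies of 1 base name and arm summed, 22 names held copies and 170 miRNAs were called. Of the other values of named miRNAs with all libraries, 839 kept their direction and side of the threshold, 33 became calls and 13 lost the call. Depth limits what can be said of low miRNAs at 6 d, where 3 reads are worth up to 3.97 CPM.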

Other observations

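The tests of a smaller heart share, over the whole list and over its epithelial members, and of other tissues were chosen after the results were seen, as were the miR-34, miR-449, cluster and miR-99, miR-100 and miR-125 miRNAs below. The log2 fold change was 2.99 ± 0.44 for miR-34c-5p, 2.11 ± 0.48 for miR-34b-5p and 3.12 ± 0.49 for miR-449a-5p, and 3 of 6 tested members of the miR-34 and miR-449 families rose and 0 fell, with miR-34a-5p at -0.48, not past the threshold. Within the miR-17-92 list, and apart from miR-92a and miR-19b, which both clusters encode, the 4 tested members of the miR-106a-363 cluster all rose by limma (median 2.47) and 3 by edgeR, whereas 0 of 6 members of miR-17-92 itself were called by limma (median 0.18), with 0 at an unadjusted p under 0.05 and 0 with edgeR. The shared miR-92a-3p rose (log2 fold change 1.20, limma adjusted p = 0.013). The difference between the clusters was not tested, and miR-18b-5p had 1 read at 0 h. The miR-99, miR-100 and miR-125 families fell in 7 of 9 members (median -2.08), miR-125a-5p by -2.96 ± 0.43 on the log2 scale.

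The higher miRNAs of other organs were weighed first. The rise remained at equal read number. Thinning kept 1.18 times the median log2 fold change of the 11 higher members, at 4.04 against 3.42, and 10 were still called. Thinning leaves each miRNA's share of the reads the same on average, and the thinned libraries were given new TMM factors. It therefore tests the sampling of reads alone, and a large drop was unlikely for members with many reads. A smaller share of heart RNA was weighed as well. The median of all 9 tested epithelial members was 4.09 (SD 1.95) and that of the 4 smooth muscle and pericyte members -0.45 (SD 0.24), 4.54 apart. Smooth muscle cells and pericytes are themselves part of the heart wall, so this gap cannot decide for or against a smaller heart share. For the whole list, which mixes organs, the comparison with smooth muscle came first. Its medians lay 2.09 apart, under the 2.29 SD of the list's members, so a smaller heart share cannot be told apart there either. RNA of other tissues in the 6 d samples may account for the pattern, with 8 of 9 epithelial and 2 of 2 skeletal muscle members higher, but only 2 of 5 liver members (40%). The skeletal muscle members, miR-206-3p and miR-133b-3p, are clustered neighbours and come from another list. Members of the other organ list outside these tissues were not counted. Of them miR-375-3p rose (3.01) and miR-128-3p fell (-1.50). The log2 fold changes of miR-9-5p (-1.56), miR-9-3p (-0.01) and miR-217-5p (0.43) were not past the threshold. The liver members not called were miR-192-5p and the low miR-194-1-3p and miR-194-2-3p. The 6 d means of these last were 0.87 and 2.28 CPM, near or under the floor of 3 reads, so the liver share is uncertain. This explanation stays open, as does the post-mortem interval itself.

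The higher miRNAs numbered 1000 or above were weighed next. Their rise also remained at equal read number, with the same limits of thinning. It kept 1.13 times the median log2 fold change of the 11 higher members that stayed in the thinned test, at 3.55 against 3.13, and 10 were still called. The other higher member, miR-8094, had 1 read at 0 h and 12 at 6 d and was filtered out by thinning, and with it counted as 0 the ratio over all 12 was also 1.13. Members whose precursor matches a structural RNA, here 13 of 71, had a median log2 fold change 1.17 above the others, or 1.13 over the 68 members whose precursor was searched. Because the 13 come from only 8 precursors, the labels were permuted by whole precursor, a test chosen after the result was seen (permutation p = 0.028, across precursors, which are not independent replicates). This is consistent with fragments of structural RNA as a candidate source for 5 of the 12 higher members. The 4 with the largest rise, miR-6538, miR-2137, miR-6236 and miR-6240, matched none of the structural RNAs searched, and full-length large ribosomal RNAs were not among those used here. Without the matching members 7 of the list rose and 12 fell, most of these falls ending under the 6 d floor of 3 reads.

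Over all tested miRNAs with a precursor (449 of 470), the log2 fold change had a Spearman rho of -0.19 with precursor GC content (permutation p = 5.0e-05, across miRNAs, which are not independent replicates), a relation too weak to settle whether GC content matters.

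The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split mixes libraries of both intervals in each group. Part of the difference between intervals then stays in the contrast, and the rest widens the spread within groups. Few calls of single miRNAs or arm ratios were therefore likely in these splits. The real split gave 178 calls, 175 of at least 2-fold and 46 arm ratios, and the highest of the other splits 0 for each with limma (up to 16 miRNAs and 4 arm ratios at an unadjusted p under 0.05), so that 1 of the 10 splits reached each. For the lists the real split gave 3 and the highest other split 4, and 5 of the 10 splits gave at least 3. List calls at the preset correlation thus arose in other splits as well. Because those splits keep part of the interval difference, they cannot show how many list calls would arise by chance.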
